A study of Mus musculus with 2 samples.

How the data were processed

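The series holds 2 single-cell RNA libraries of wild-type mouse liver, WT 007 (replicate 1) and WT 014 (replicate 2), in a single group, so classes of cells within the libraries were compared rather than conditions. Per the labels' protocols, the bile duct and vessel tree was freed by collagenase perfusion and digestion, passed through filters, and sorted for cells negative for Epcam, CD31, CD45 and CD11b, and libraries were made with the 10x Genomics 3' v2 kit. Per the submitters' processing notes, Cell Ranger 2.1.1 and the build mm10 were used. The deposited matrices hold raw UMI counts per gene and cell barcode (whole numbers, lowest barcode total 500), per the file headers. Of 33696 gene identifiers, 1684 (5.00%) were absent from GENCODE M21, so another annotation was used, and genome positions are not used here. The layout of the gene files and the start of the barcodes are those of later Cell Ranger versions and kits, so the version and kit named above are in doubt. Whether the libraries came from separate animals, and the animals' age and sex, are not given in the sources used here. Xist stood at 0.078 and 0.234 CPM and Ddx3y at 155 and 165, a male pattern in both.

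Replicate 1 held 5854 barcodes with 69594541 UMIs and replicate 2 held 2569 with 31063966. Over 8072 genes the libraries correlated at r = 0.991 (log2 CPM), they shared 2 barcodes, and a chi-square statistic of 54.6 per gene showed more difference than a library counted 2 times would. Barcodes with fewer than 500 genes, fewer than 1000 UMIs or over 10% mitochondrial UMIs were removed, 911 (15.6%) and 437 (17.0%). Scrublet in scanpy scored doublets within each library. Its own threshold marked 5 cells (0.101%) of replicate 1, under the preset minimum of 0.5%, so the 195 highest scores (3.94%, from 0.8% per 1000 cells) were removed instead, and its own threshold was kept in replicate 2 (23 cells, 1.08%). Cells kept numbered 4748 and 2109, with medians of 13283 and 14120 UMIs, 3466 and 3609 genes, and 2.63% and 2.71% mitochondrial UMIs.

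Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen within libraries. Mitochondrial, ribosomal, Xist and Y-linked genes and the 446 genes of 23 lists (none in more than 1 list) were kept out, so that list genes had no part in forming the clusters. Both libraries were clustered together without integration, with 30 components, 20 neighbours and Leiden resolution 0.8 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9). The lists, 12 marker sets, panel, filters, tests and most alternatives were chosen before the data were examined. The naming rule was set afterwards. A marker counted as raised at 2-fold over the mean of the other clusters (after adding 20 CPM) and at least 50 CPM. A class name needed 3 or more raised markers, at least 50% of its set, and more than any other class. Cluster 15, with 8 endothelial markers raised, stayed unnamed because its median of 4372.5 UMIs was low and none of its 10 leading genes was a marker. Names carry "-like" because they rest on these markers, and the marker genes themselves are not given as results, apart from genes of the sort.

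Raw counts were summed per library and class. Classes with at least 20 cells in each library (portal fibroblast-like, hepatic stellate cell-like, vascular smooth muscle-like, mesothelial-like and endothelial-like) entered 1 edgeR fit (R 4.3.3, edgeR 4.0.16, limma 3.58.1) with TMM scaling, filterByExpr and the library as a block, since the classes come from the same libraries. The fit held 13548 genes (405 list genes, 11553 outside the clustering) with 4 residual degrees of freedom, and that of the portal fibroblast-like clusters 11685 genes with 2. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in the quasi-likelihood test (two-sided). Lists were tested by camera on the same fit with a preset correlation of 0.01, adjusted over the 23 lists, with the correlation estimated per list and fry as alternatives. The fry p used here tests direction on balance. Numbers of list members higher or lower come from the gene test throughout, and the adjusted p of a list from camera. In a test on simulated data with 50 changed genes per size, the portal fibroblast-like against stellate-like comparison recovered 19 at 1.5-fold, 46 at 2-fold, 50 at 4-fold and 50 at 8-fold, and called 13 of 12882 unchanged genes. The changed genes had mean fitted counts over 50, as many were raised as lowered, and counts were drawn from the fitted dispersions. These rates therefore do not cover genes with few counts or comparisons in which a large part of the genes differ. Across 161 pairs of list and comparison the median, the mean and the test differed in sign in 25, of which 1 was called.

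A panel of 15 genes, of which 1 is not reported here, is named in every comparison. Beyond it, the rule named, per list and direction, the member with the largest log2 fold change among those called, the same in direction in both libraries, and at 50 CPM or more in the higher class, limited to the 15 largest in the comparison with stellate-like cells and 6 in each other. Folds against a class with 0 counts are given against a floor of 3 counts over both libraries. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Near-identical pairs (Hspa1a and Hspa1b, C1ra and C1rb) may share reads, and their levels are uncertain. Ly6a and Ly6c1 belong to one gene family without being near-identical. Read sharing was not measured for any pair.

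Alternatives changed 1 choice at a time. They were DESeq2 1.42.0 in place of edgeR, its size factors in edgeR, no filter on low counts, a fit of the compared classes only, no replicate block, and cells thinned to 2000 UMIs. Other clusterings had resolutions of 0.4 and 1.5, list genes allowed among the variable genes, genes scaled within libraries, no doublet removal, a mitochondrial limit of 5%, every barcode kept, and each library left out. In a further setting the counts were split at random into 2 equal parts, with clusters from 1 part and sums from the other. Thinning left out 3 and 0 portal fibroblast-like, 1 and 1 stellate-like, 3 and 2 smooth muscle-like, 2 and 1 endothelial-like and 44 and 22 unnamed cells, and 0 mesothelial-like cells.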

Results

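The genes of the proteins used to exclude cells in the sort were read first. Transcripts of Epcam (an epithelial surface protein of bile duct cells) were found in 6 of 4748 cells of replicate 1 and 3 of 2109 cells of replicate 2, and 4 of the 45 and 2 of the 51 mesothelial-like cells held them. Ptprc (CD45, carried by blood-derived cells) was found in 1 cell of replicate 1 and 0 of replicate 2, and Itgam (CD11b, of myeloid cells) in 7 cells and 1 cell. Pecam1 (CD31, of vessel lining cells) was the exception, with transcripts in 6.55% of replicate 1 and 5.97% of replicate 2 cells. It was found in 2.68% and 2.95% of portal fibroblast-like cells, at 2.39 and 2.23 CPM. Levels in endothelial-like cells are not given, since Pecam1 is 1 of the 8 markers that named them.

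Portal fibroblast-like cells (clusters 2, 4 and 7) were the largest named class, followed by hepatic stellate cell-like and vascular smooth muscle-like cells, in the clustering used for the tests. With list genes allowed among the variable genes, stellate-like cells outnumbered them in both libraries (28.1% and 24.8% against 22.3% and 24.5%), and with the expected doublet rate in both libraries they did so in replicate 1 (1216 against 997 cells). Portal fibroblast-like cells made up 30.6% of replicate 1 (exact 95% interval 29.3 to 32.0) and 40.2% of replicate 2 (38.1 to 42.3), or 1455 and 848 cells. Hepatic stellate cell-like cells made up 25.7% and 22.9%, vascular smooth muscle-like cells 11.7% and 7.54%, endothelial-like cells 2.72% and 1.99%, mesothelial-like cells 0.948% and 2.42%, and Schwann or glial-like cells 0.548% and 0.142%. No cluster took the name of cholangiocytes, hepatocytes, macrophages, lymphocytes, neutrophils or monocytes, or erythroid cells, although cells too few to form a cluster would not be seen this way. With every barcode kept, a hepatocyte-like cluster held 83 barcodes (1.42%) of replicate 1 and 8 (0.311%) of replicate 2. The unnamed clusters held 27.7% and 24.8% of cells. That share depended on how many markers a cluster had to raise, a choice made after the clusters had been seen. Dissociation, filtering and the sort against Epcam, CD31, CD45 and CD11b set these shares along with the tissue. The intervals cover counting error only, and the portal fibroblast-like shares of the libraries lay further apart than those intervals.

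**Figure D1:**
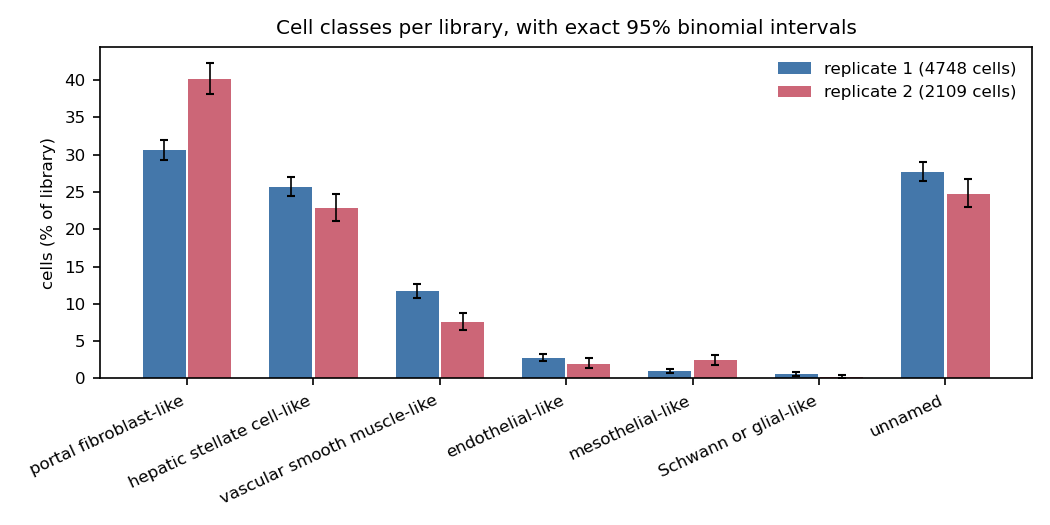
Share of cells (percent, linear axis from 0) per cell class in each library, with exact 95% binomial intervals as error bars. In the clustering drawn here portal fibroblast-like cells made up 30.6% and 40.2%.

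Compared with hepatic stellate cell-like cells, portal fibroblast-like cells carried more collagen, elastic fibre, basement membrane, growth factor and Wnt pathway genes. Each list called by camera on the edgeR fit lost its call, at adjusted p from 0.0799 to 0.412 with an estimated correlation. Stellate-like cells, the vitamin A storing pericytes of the sinusoids, held the BMP ligands Bmp10 and Gdf2 (circulating ligands that keep liver endothelium quiescent), the Wnt amplifier Rspo3 (an inducer of pericentral hepatocyte genes), vasoactive receptors and interferon-response genes. Of 405 list genes tested, 216 were higher in portal fibroblast-like cells and 110 lower. Among the 11553 tested genes that had no part in the clustering, 2618 were higher and 2253 lower.

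The fixed panel divided as follows in portal fibroblast-like against stellate-like cells, with values given as log2 fold change ± SE. Here and below, the SE was back-calculated as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It can understate the uncertainty of genes with few counts in a class. Higher were Col15a1 (a collagen of vessel and duct basement membranes, 7.79 ± 0.26), Slit2 (a repulsive cue for axons and migrating cells, 7.53 ± 0.45), Cd34 (a surface sialomucin of progenitor and adventitial cells, 7.10 ± 0.22), Gli1 (the transcriptional readout of Hedgehog signals, 4.45 ± 0.31) and Eln (elastin, 3.46 ± 0.30). Col1a1 (the chief collagen of scar, 3.44 ± 0.23), Il33 (an alarmin for innate lymphoid cells, 2.02 ± 0.28), Ly6a (Sca-1, 1.90 ± 0.23) and Pdgfra (a receptor of fibroblasts, 1.22 ± 0.17) were higher as well. The libraries taken singly, with a prior count of 2, gave 6.17 and 6.58 for Slit2 (at 0.287 and 0 CPM in stellate-like cells, so that its fold is uncertain), 4.24 and 3.48 for Gli1 and 2.82 and 1.28 for Il33. Lower were Rspo3 (-5.79 ± 0.43), Hand2 (a transcription factor of stellate cell identity, -2.46 ± 0.18) and Cxcl12 (a chemokine that holds lymphoid and progenitor cells, -0.60 ± 0.16). The highest adjusted p of these genes was 0.00588, for Cxcl12, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Pdgfrb (-0.35, adjusted p = 0.104) and Des (-0.07, adjusted p = 0.79), both often used as stellate cell genes, were not called by that test. Cd34 stood at 433 ± 57.7 CPM (mean ± SD, n = 2) against 3.23 ± 0.014, and Col15a1 at 491 ± 26.9 against 2.26 ± 0.467. These low stellate-like levels, and the size of both folds, depend on the naming rule. With looser naming the smooth muscle-like class kept its cells (556 and 159). Stellate-like against smooth muscle-like cells then went from -2.46 to 0.46 for Cd34 and from -3.19 to 0.06 for Col15a1. Whether any reads of Ly6a were counted for its relative Ly6c1 was not measured.

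**Figure D2:**
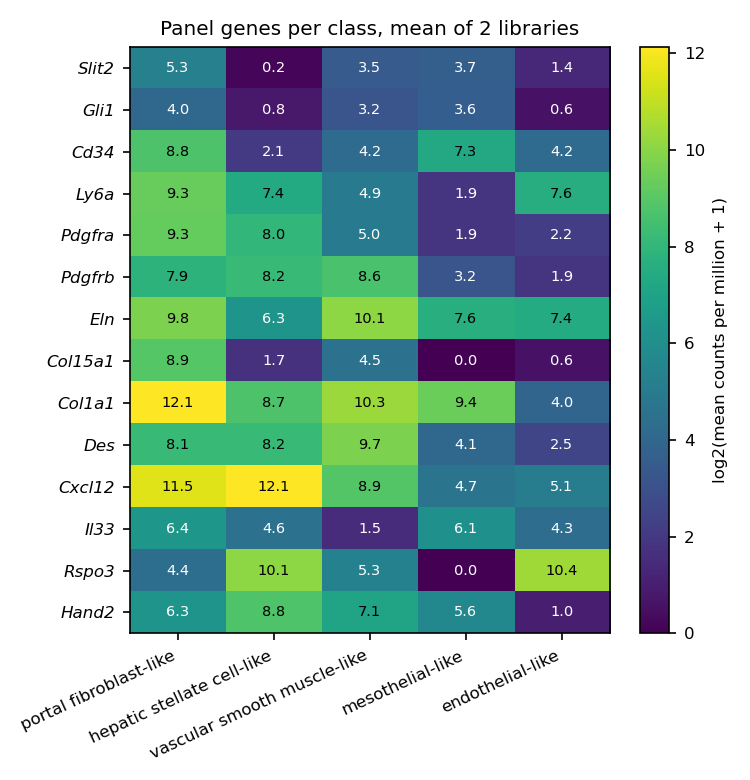
Levels of panel genes, as log2 of mean CPM plus 1, in the cell classes that entered the fit. Slit2, Cd34 and Col15a1 were highest in portal fibroblast-like cells and at 3.23 CPM or less in stellate-like cells, under the naming rule used for the tests. The low Cd34 and Col15a1 of stellate-like cells depended on that rule.

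Matrix lists moved together toward portal fibroblast-like cells. By the gene test, 7 of 9 fibrillar collagens were higher, 1 lower and 1 not called, with Col1a2 at 2.60 ± 0.28 and Col3a1 at 1.85 ± 0.16. By camera on the edgeR fit with Benjamini-Hochberg adjustment, that list had adjusted p = 0.00182, or adjusted p = 0.0989 with an estimated correlation. Other interstitial collagens gave 8 of 10 higher and 0 lower (adjusted p = 0.000404, or adjusted p = 0.0799 with an estimated correlation). Among them were Col6a5 (7.34 ± 0.34) and Col6a6 (7.71 ± 0.37; 7.70 and 6.82 by library), chains of the microfibrillar collagen that anchors cells. Elastic fibre genes gave 11 of 15 higher and 2 lower (adjusted p = 0.000636, or adjusted p = 0.0799 with an estimated correlation). Fbln1 (a fibulin of vessel walls, 7.43 ± 0.39) and Fbn2 (a microfibril scaffold, 6.53 ± 0.26) led them, with Efemp1 (-2.50 ± 0.23) on the opposite side. Basement membrane genes gave 13 of 21 higher and 4 lower (adjusted p = 0.0012, or adjusted p = 0.118 with an estimated correlation), including Col4a5 (5.59 ± 0.21) and Lama4 (5.48 ± 0.25). Proteoglycans gave 13 of 16 higher and 2 lower (adjusted p = 0.000116, or adjusted p = 0.0799 with an estimated correlation). Fmod (a binder of collagen fibrils, 7.19 ± 0.29; 7.78 and 6.41 by library) and Has1 (a hyaluronan synthase, 4.73 ± 0.30) rose, and Dcn (-0.88 ± 0.19) fell. Matrix proteases and inhibitors gave 16 of 20 higher and 0 lower (adjusted p = 3.89e-06, or adjusted p = 0.188 with an estimated correlation), with Serpinf1 (an inhibitor of vessel growth, 7.88 ± 0.36; 8.38 and 6.92 by library) and Mmp3 (stromelysin, 7.49 ± 0.23). Collagen processing genes gave 7 of 15 higher and 1 lower (adjusted p = 0.0197, or adjusted p = 0.252 with an estimated correlation), with Pcolce2 (a procollagen trimming helper) at 7.03 ± 0.35, or 7.84 and 5.57 by library.

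Secreted signals followed. Growth factors gave 16 of 24 higher and 0 lower (adjusted p = 3.52e-05 by camera on the edgeR fit, or adjusted p = 0.0799 with an estimated correlation), with Ptn (a heparin-binding growth factor, 8.20 ± 0.25) and Vegfd (a lymphatic growth factor, 6.14 ± 0.22). Chemokines and cytokines gave 17 of 24 higher and 4 lower (adjusted p = 0.000411, or adjusted p = 0.258 with an estimated correlation). Ccl11 (an eosinophil attractant, 6.13 ± 0.22), Il6 (5.47 ± 0.22) and Tslp (4.79 ± 0.19) were higher and Cxcl10 (-2.39 ± 0.18) lower. Complement gave 9 of 12 higher and 3 lower (adjusted p = 0.0123, or adjusted p = 0.176 with an estimated correlation), led by C7 (8.74 ± 0.29) and C3 (7.58 ± 0.23). Wnt pathway genes gave 16 of 23 higher and 3 lower (adjusted p = 0.000404, or adjusted p = 0.244 with an estimated correlation). The secreted antagonists Sfrp1 (8.43 ± 0.24) and Wif1 stood out, the latter with 2 counts in stellate-like cells and a ratio of 476 (counting interval 132 to 3937). BMP and TGF-beta genes gave 16 of 24 higher and 5 lower (adjusted p = 0.0222, or adjusted p = 0.275 with an estimated correlation). There Tgfb3 (3.02 ± 0.23) and Bmp4 (1.57 ± 0.18) were higher, against Bmp10 (-8.99 ± 0.26; -7.96 and -8.63 by library) and Gdf2 (-7.97 ± 0.26). Hedgehog genes were not called as a list (7 of 12 higher, 3 lower, adjusted p = 0.134) although the coreceptor Boc (4.31 ± 0.19) and Gli2 (3.59 ± 0.32) were. Axon guidance genes split, with 13 of 25 higher and 9 lower (adjusted p = 0.134), from Slit3 (7.14 ± 0.25; 6.36 and 6.29 by library) to Ntn1 (netrin-1, -2.83 ± 0.18) and the Slit receptor Robo2 (-2.11 ± 0.16). Notch genes did too (2 of 13 higher, 4 lower, adjusted p = 0.627), with Notch3 at 2.41 ± 0.20 and Notch1 at -2.34 ± 0.17.

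Vasoactive receptors and signalling genes were lower in portal fibroblast-like than in stellate-like cells, at 14 of 21 lower and 3 higher (adjusted p = 1.72e-05 by camera on the edgeR fit, or adjusted p = 0.0799 with an estimated correlation). Rgs5 (a brake on contractile G-protein signals of pericytes, -5.82 ± 0.33), Agtr1a (the angiotensin receptor, -3.35 ± 0.21) and Ednrb (an endothelin receptor, -2.53 ± 0.17) were among them. Antigen presentation and interferon genes gave 18 of 20 lower and 2 higher (adjusted p = 3.89e-06, or adjusted p = 0.208 with an estimated correlation), with Ifit3 (-4.97 ± 0.27; -5.26 and -4.67 by library), Isg15 (-2.44 ± 0.23) and H2-K1 (-1.64 ± 0.16). Dissociation and immediate early genes, a measure of handling stress, moved the same way, with 9 of 17 lower and 1 higher (adjusted p = 0.0182, or adjusted p = 0.412 with an estimated correlation). Hspa1a (-3.17 ± 0.33, not separable with certainty from its copy Hspa1b) and Jun (-1.40 ± 0.20) were among them. The remaining lists were not called by camera on the edgeR fit. Retinoid and lipid droplet genes gave 5 of 14 higher and 6 lower (adjusted p = 0.317), with Plin2 (a droplet coat protein, -2.60 ± 0.15) lower and Rdh10 (1.73 ± 0.15) higher. Mesenchymal transcription factors gave 17 of 28 higher and 9 lower (adjusted p = 0.101), with Ebf1 (5.81 ± 0.25) against Lhx2 (-5.29 ± 0.17) and Nr1h5 (-7.88 ± 0.28, with -7.42 in replicate 2 and a smaller fall in replicate 1). Progenitor surface genes gave 9 of 16 higher and 4 lower (adjusted p = 0.0647), contractile genes 8 of 20 and 6 (adjusted p = 0.688), and proliferation genes 0 of 6 and 3 (adjusted p = 0.0647). Adjusted over the list alone, the counts differed in 3 lists, at 16 higher and 1 lower for growth factors, 18 and 4 for chemokines and cytokines, and 9 and 5 for progenitor surface genes. Genes printed here beyond the panel and the largest per list were chosen after their values had been seen. With the library as a block, the p-values measure only how far class differences varied between these libraries, with variances moderated over genes. They cannot be read as spread between animals, since the labels do not say that the libraries came from separate animals.

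**Figure D3:**
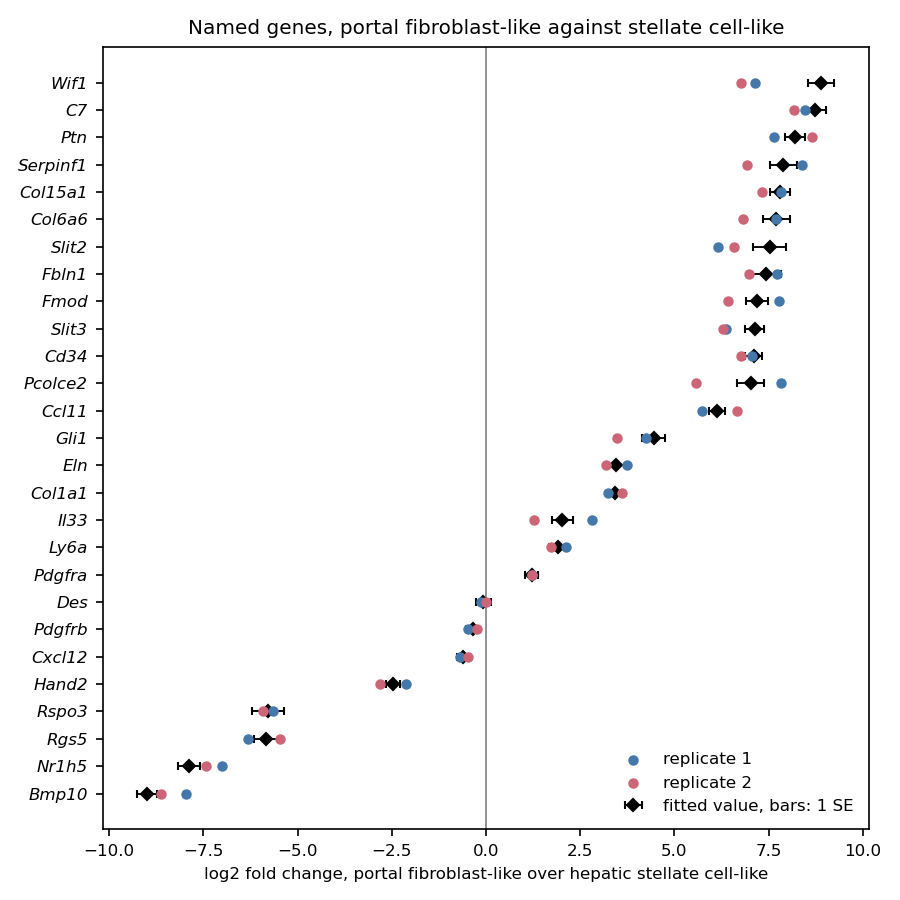
Log2 fold change of named genes in portal fibroblast-like against stellate-like cells, with the fitted value, its SE (back-calculated from the F statistic), and the value of each library, drawn toward 0 at low counts by a prior count of 2. Col15a1 at 7.79 and Bmp10 at -8.99 lay near opposite ends, and the fitted values of Wif1 and Slit2 rest on 2 counts and on 0.287 and 0 CPM in stellate-like cells.

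**Figure D4:**
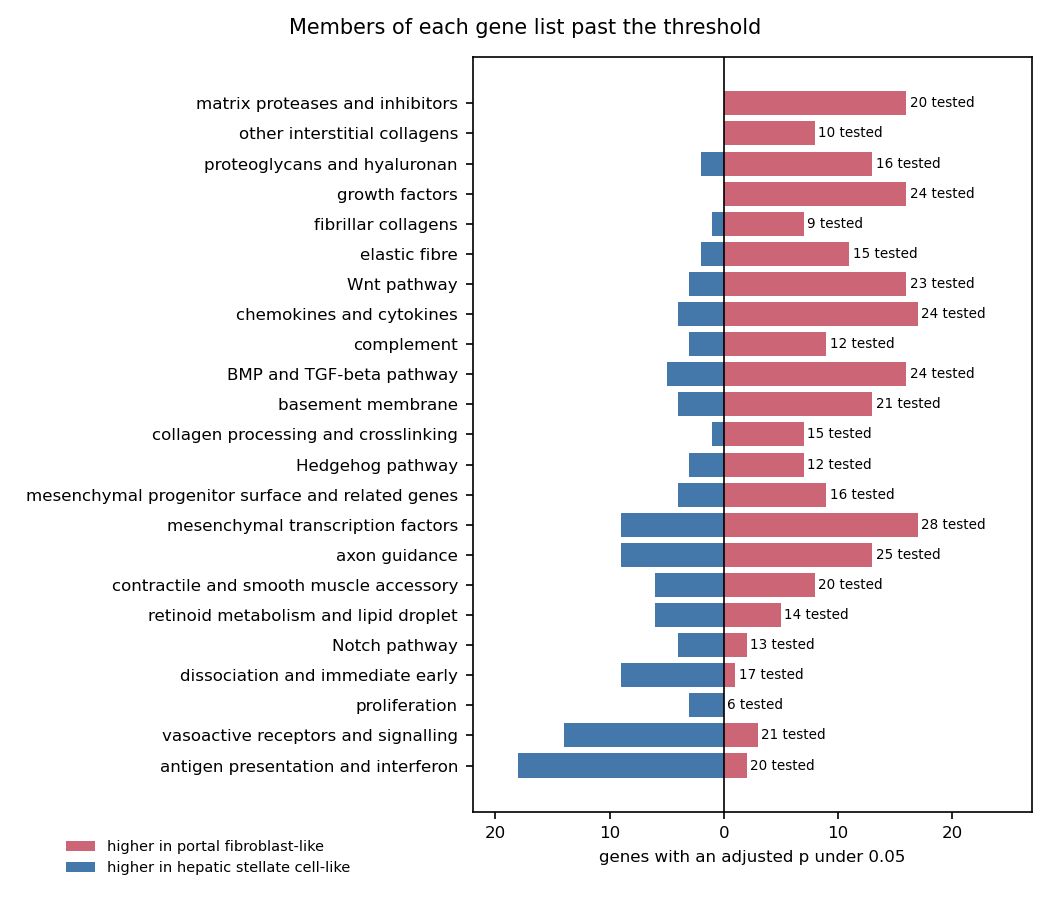
Numbers of genes with an adjusted p under 0.05 (edgeR quasi-likelihood test) per gene list, higher in portal fibroblast-like cells to the right and higher in stellate-like cells to the left, with the number tested beside each bar. Lists are in the order of higher minus lower genes over genes tested, with matrix proteases (16 of 20 higher) and other interstitial collagens (8 of 10 higher) at one end and antigen presentation and interferon genes (18 of 20 lower) at the other.

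Against vascular smooth muscle-like cells, the contractile cells of artery and vein walls, portal fibroblast-like cells were set apart by complement, chemokines and collagens on the high side and by contractile and Notch genes on the low side. Of the lists called by camera on the edgeR fit, complement alone stayed called, and these others had adjusted p from 0.0506 to 0.148 with an estimated correlation. Of the list genes 196 were higher and 96 lower, and outside the clustering 1812 genes were higher and 1489 lower. In the panel, Il33 (5.41 ± 0.47), Cd34 (4.64 ± 0.20), Col15a1 (4.60 ± 0.22), Pdgfra (4.38 ± 0.21), Ly6a (4.35 ± 0.27), Cxcl12 (2.64 ± 0.17), Slit2 (1.98 ± 0.28), Col1a1 (1.83 ± 0.21) and Gli1 (0.94 ± 0.24) were higher. Des (a muscle intermediate filament, -1.56 ± 0.21), Hand2 (-0.78 ± 0.18) and Pdgfrb (-0.76 ± 0.17) were lower. The highest adjusted p of these genes was 0.00564, for Gli1, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Eln (-0.25, adjusted p = 0.51) went in opposite directions in the libraries, at -0.68 and 0.34, and Rspo3 (-0.92, adjusted p = 0.0988), at -0.01 and -1.69 in the libraries, was not called either.

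Contractile genes gave 18 of 20 lower and 0 higher in this comparison (adjusted p = 4.76e-17 by camera on the edgeR fit, or adjusted p = 0.0506 with an estimated correlation). Kcnmb1 (a potassium channel subunit that relaxes vessel walls, -6.16 ± 0.25; -5.95 and -5.43 by library), Myocd (the master coactivator of smooth muscle genes, -5.13 ± 0.20) and Myl9 (-3.70 ± 0.22) were among them. Notch genes gave 7 of 13 lower and 0 higher (adjusted p = 0.000415, or adjusted p = 0.148 with an estimated correlation), as in the feedback gene Nrarp (-6.24 ± 0.30) and Notch3 (the mural cell receptor, -3.57 ± 0.19). Vasoactive genes gave 12 of 21 lower and 4 higher (adjusted p = 0.00518, or adjusted p = 0.0914 with an estimated correlation), with Rgs4 at -6.44 ± 0.29, or -6.26 and -5.78 by library. Complement was the list called under both correlations, with 12 of 12 higher (adjusted p = 4.7e-11, or adjusted p = 0.0428 with an estimated correlation), as in C7 (6.39 ± 0.26; 6.88 and 5.60 by library) and C3 (6.38 ± 0.22). Chemokines and cytokines gave 16 of 24 higher and 2 lower (adjusted p = 1.47e-05, or adjusted p = 0.148 with an estimated correlation), with Cxcl14 at 8.33 ± 0.35, or 7.50 and 7.62 by library. Hedgehog genes gave 10 of 12 higher and 0 lower (adjusted p = 0.00163, or adjusted p = 0.0914 with an estimated correlation), including Cdon (a ligand coreceptor, 3.24 ± 0.28) and Gli2 (1.08 ± 0.29). Wif1, with 2 counts in smooth muscle-like cells, had a ratio of 216 (counting interval 59.8 to 1789). Adjusted over the list alone, the counts were 18 lower for contractile genes, 7 for Notch, 10 higher for Hedgehog and 12 for complement, as over all genes, and 17 higher and 3 lower for chemokines and cytokines.

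Matrix lists other than basement membrane were higher in portal fibroblast-like than in smooth muscle-like cells. By camera on the edgeR fit they ran from elastic fibre (11 of 15 higher, 1 lower, adjusted p = 6.64e-06) and fibrillar collagens (8 of 9 higher, 0 lower, adjusted p = 3.77e-05) to other interstitial collagens (8 of 10 higher, 1 lower, adjusted p = 6.86e-05). With an estimated correlation each had adjusted p = 0.0506. Collagen processing (11 of 15 higher, 0 lower, adjusted p = 0.000145), proteases (12 of 20 higher, 1 lower, adjusted p = 0.000425) and proteoglycans (11 of 16 higher, 3 lower, adjusted p = 0.00654) followed. Adjusted p of these lists ran from 0.0889 to 0.175 with an estimated correlation. Fbln5 (a fibulin needed to lay down elastic fibres, 2.27 ± 0.16), Loxl1 (an elastin crosslinking oxidase, 1.91 ± 0.15), Mmp2 (4.26 ± 0.27), Dcn (2.35 ± 0.20) and Lum (3.19 ± 0.20) were higher, while Sdc1 (-2.22 ± 0.14) was lower. Axon guidance (15 of 25 higher, 5 lower, adjusted p = 0.00506), Wnt (14 of 23 higher, 4 lower, adjusted p = 0.0123) and growth factor genes (14 of 24 higher, 6 lower, adjusted p = 0.0334) were called by the same test. For these lists adjusted p ran from 0.147 to 0.361 with an estimated correlation. Robo2 (4.19 ± 0.27), Sfrp1 (5.72 ± 0.21) and Ptn (4.13 ± 0.20) were higher and Angpt2 (a vessel destabilising factor, -3.60 ± 0.23) lower. Adjusted over the list alone, elastic fibre had 13 higher, collagen processing 12, proteoglycans 12 and Wnt 15 higher and 5 lower. Not called were basement membrane, retinoid, BMP and TGF-beta, progenitor surface, transcription factor, dissociation, antigen presentation and proliferation lists, with adjusted p from 0.0572 to 0.883. In all lists 209 genes were higher and 103 lower when adjusted over the list alone.

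Hepatic stellate cell-like against vascular smooth muscle-like cells separated retinoid and interferon genes of the sinusoidal pericyte from contractile, protease, basement membrane and growth factor genes of the vessel wall. Each list called by camera on the edgeR fit lost its call here too, at adjusted p from 0.278 to 0.427 with an estimated correlation. List genes numbered 140 higher and 172 lower in stellate-like cells, and outside the clustering 1944 genes were higher and 2273 lower. In the panel Rspo3 (4.87 ± 0.43; 5.62 and 4.21 by library), Il33 (3.38 ± 0.55; 2.43 and 3.98), Cxcl12 (3.23 ± 0.18), Pdgfra (3.16 ± 0.20), Ly6a (2.45 ± 0.26; 1.87 and 3.16) and Hand2 (1.69 ± 0.18) were higher. Slit2 (-5.55 ± 0.61; -4.05 and -5.07 by library), Eln (-3.71 ± 0.30; -4.43 and -2.85), Gli1 (-3.51 ± 0.38; -3.26 and -2.67), Col15a1 (-3.19 ± 0.29), Cd34 (-2.46 ± 0.25), Col1a1 (-1.61 ± 0.21) and Des (-1.49 ± 0.21) were lower. Their highest adjusted p was 7.03e-05, for Il33, and Pdgfrb was not called (-0.41, adjusted p = 0.0646), by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The lower Cd34 and Col15a1 were not kept when clusters were named more loosely (0.46 and 0.06). Of portal fibroblast-like, smooth muscle-like and stellate-like cells, Slit2 and Gli1 were thus highest in the first and lowest in the last.

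Antigen presentation and interferon genes gave 17 of 20 higher and 0 lower in stellate-like against smooth muscle-like cells (adjusted p = 7.73e-07 by camera on the edgeR fit, or adjusted p = 0.278 with an estimated correlation), with Ifit3 at 4.08 ± 0.26 and B2m at 1.94 ± 0.16. Dissociation genes again moved the same way (13 of 17 higher, 2 lower, adjusted p = 0.00554, or adjusted p = 0.427 with an estimated correlation), with Hspa1a at 2.17 ± 0.32. Retinoid and lipid droplet genes gave 8 of 14 higher and 3 lower (adjusted p = 0.0346, or adjusted p = 0.278 with an estimated correlation), including Aldh1a3 (an enzyme that makes retinoic acid, 4.80 ± 0.30) and Plin2 (1.90 ± 0.16). Complement gave 7 of 12 higher and 3 lower (adjusted p = 0.038, or adjusted p = 0.278 with an estimated correlation), with Masp1 at 4.46 ± 0.22. Contractile genes gave 16 of 20 lower and 1 higher (adjusted p = 2.3e-08, or adjusted p = 0.278 with an estimated correlation), led by Myocd (-8.88 ± 0.32; -7.76 and -7.31 by library). Lower as lists were also proteases (12 of 20, adjusted p = 0.00554), basement membrane (11 of 21, adjusted p = 0.00722), growth factors (15 of 24, adjusted p = 0.00722) and other interstitial collagens (6 of 10, adjusted p = 0.0346). With an estimated correlation these lists had adjusted p from 0.278 to 0.411. Higher in those lists were 2, 3, 3 and 2 genes. Examples were Serpinf1 (-4.76 ± 0.35), Col4a5 (-4.87 ± 0.21), Bdnf (-4.18 ± 0.22) and Col6a2 (-1.46 ± 0.17). Among lists that were not called, Bmp10 (3 counts in smooth muscle-like cells, ratio 656, counting interval 224 to 3182) and Cxcl14 (7.79 ± 0.36; 7.30 and 6.73 by library) were higher. Aspn (-8.60 ± 0.41; -8.91 and -7.34), Slit3 (-7.54 ± 0.26; -6.80 and -6.64) and Nrarp (-7.43 ± 0.37; -6.64 and -6.37) were lower. Adjusted over the list alone, dissociation genes had 14 higher and 2 lower and growth factors 4 higher and 15 lower, and the other called lists kept their counts. The 14 lists that were not called spanned adjusted p from 0.0696 to 0.956.

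Portal fibroblast-like cells differed from mesothelial-like cells, the lining of the liver capsule, by the receptors Pdgfra and Pdgfrb and by chemokines, proteases and mesenchymal transcription factors. No list called there by camera on the edgeR fit kept its call, at adjusted p from 0.0597 to 0.305 with an estimated correlation. List genes numbered 229 higher and 65 lower, and outside the clustering 2072 genes were higher and 1629 lower. In the panel Ly6a (7.88 ± 0.47), Pdgfra (7.82 ± 0.36), Cxcl12 (6.90 ± 0.24), Pdgfrb (4.84 ± 0.32), Des (4.21 ± 0.32; 3.41 and 5.98 by library), Col1a1 (2.83 ± 0.23; 2.30 and 3.44), Eln (2.09 ± 0.30), Slit2 (1.72 ± 0.44; 0.98 and 4.26), Cd34 (1.44 ± 0.18) and Hand2 (0.68 ± 0.24) were higher. The highest adjusted p of these genes was 0.0333, for Hand2, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Ly6a and Pdgfra each stood at 2.66 ± 1.82 CPM (mean ± SD, n = 2) in mesothelial-like cells, so the size of their folds rests on few counts. Gli1 (0.44, adjusted p = 0.384) and Il33 (0.34, adjusted p = 0.485) were not called. With 0 counts in the 96 mesothelial-like cells, Col15a1 was at least 182-fold higher, Itga8 (an integrin of mural cells) at least 93.8-fold and Pcolce2 at least 64.6-fold. Prrx1 (a limb and fibroblast homeobox factor) was at least 35.9-fold higher, Wif1 at least 19.9-fold, Heyl (a Notch target) at least 17.5-fold and Rspo3 at least 7.38-fold.

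Chemokines and cytokines gave 18 of 24 higher and 1 lower against mesothelial-like cells (adjusted p = 1.02e-10 by camera on the edgeR fit, or adjusted p = 0.0849 with an estimated correlation), with Il6 (6.17 ± 0.27) and Ccl7 (a monocyte attractant, 5.73 ± 0.34). Proteases gave 17 of 20 higher and 0 lower (adjusted p = 4.03e-10), other interstitial collagens 10 of 10 (adjusted p = 2.84e-07) and transcription factors 22 of 28 and 2 (adjusted p = 5.43e-07). Adjusted p of these lists ran from 0.0597 to 0.0768 with an estimated correlation. Serpine2 (5.68 ± 0.29), Col12a1 (2.96 ± 0.35) and Tcf21 (a factor of fibroblast and stellate lineages, 7.57 ± 0.27) were examples. Fibrillar collagens (7 of 9 higher, 0 lower, adjusted p = 9.05e-06), collagen processing (11 of 15 and 0, adjusted p = 1.3e-05), vasoactive (15 of 21 and 2, adjusted p = 0.000118) and proteoglycan genes (10 of 16 and 1, adjusted p = 0.00298) went the same way. For these lists adjusted p ran from 0.0597 to 0.0768 with an estimated correlation. Growth factors (13 of 24 higher, 5 lower, adjusted p = 0.00451), elastic fibre (10 of 15 and 4, adjusted p = 0.00465) and contractile genes (9 of 20 and 2, adjusted p = 0.0133) were called too. With an estimated correlation these lists had adjusted p from 0.0768 to 0.305. Col3a1 (2.32 ± 0.16) and Abcc9 (a potassium channel subunit of pericytes, 6.06 ± 0.30) were higher. In lists not called by that test, mesothelial-like cells held more Aldh1a2 (the retinoic acid enzyme of mesothelium, -4.05 ± 0.27), Rspo1 (-4.89 ± 0.16) and Cfb (-3.56 ± 0.18). Adjusted over the list alone, the higher counts became 18 for proteases, 23 for transcription factors, 13 for collagen processing and 10 for contractile genes, and proteoglycans and growth factors gained 1 lower gene each. The 12 lists not called had adjusted p from 0.0666 to 0.82.

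Inside the portal fibroblast-like class, cluster 2 (18.2% and 29.3% of the libraries), cluster 4 (8.28% and 8.39%) and cluster 7 (4.17% and 2.56%) differed in surface, signalling and matrix genes. Each was tested against the mean of the others, with 382 list genes tested and 2 residual degrees of freedom. The results of the clusters are therefore not independent, and a gene high in a single cluster tends to come out lower in the others. Cluster 2 carried vasoactive, Notch and interferon genes and less collagen, cluster 4 carried Slit2, Gli1, Wif1 and Dkk2, and cluster 7 carried Scara5, Mfap5 and Has1. Under camera with an estimated correlation 0 lists were called in clusters 2, 4 and 7, against 1, 1 and 3 lists at an unadjusted p under 0.05. By fry 12, 0 and 9 lists were called, and 14, 13 and 10 at an unadjusted p under 0.05. Adjusted over the list alone, the list genes higher and lower were 123 and 132 in cluster 2, 105 and 102 in cluster 4, and 113 and 107 in cluster 7. Since the clusters were drawn from the same cells, only genes kept out of the clustering are given, and the clusters are not compared with outside data.

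Cluster 2 held 101 list genes higher and 106 lower, and outside the clustering 496 and 444. Cxcl12 (1.22 ± 0.13), Ly6a (0.84 and 1.23 by library), Des (0.77 ± 0.12) and Pdgfrb (0.71 ± 0.12) were higher. Lower were Slit2 (-2.30 ± 0.23), Cd34 (-1.03 ± 0.10), Col1a1 (-0.90 ± 0.10), Rspo3 (-0.85 ± 0.17), Col15a1 (-0.60 ± 0.11) and Eln (-0.44 ± 0.11). Gli1 (-0.38), Pdgfra (0.12), Il33 (-0.35; -0.63 and 0.26 by library) and Hand2 (0.15) were not called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p from 0.223 to 0.602. In that test the called panel genes had adjusted p of 0.0245 (Eln) or less. Ednrb (4.52 ± 0.19) led the higher genes. Cxcl13 (a B cell attractant), with 0 counts in cluster 2, was at least 405-fold lower than in clusters 4 and 7 together. Of their 655 counts 654 were in cluster 7, so this reflects cluster 7. The Wnt antagonist Dkk2 (-6.05 ± 0.41; -5.88 and -3.89 by library), the microfibril gene Mfap5 (-4.51 ± 0.31; -3.92 and -5.33), the tetraspanin Cd9 (-3.32 ± 0.13) and Has1 (-2.60 ± 0.14) were lower. By camera on the edgeR fit, interferon genes (12 of 19 higher, 0 lower, adjusted p = 4.56e-12), Notch genes (5 of 9 and 0, adjusted p = 2.19e-08), vasoactive genes (11 of 20 and 2, adjusted p = 5.13e-07) and contractile genes (8 of 19 and 3, adjusted p = 0.00224) were higher. Each of these lists had adjusted p = 0.218 with an estimated correlation. Ifit3 (2.15 ± 0.16), Notch1 (1.91 ± 0.17) and Gucy1a1 (a nitric oxide receptor subunit, 2.48 ± 0.14) were examples. Wnt genes (0 of 20 higher, 10 lower, adjusted p = 2.61e-07) and fibrillar collagens (0 of 8 and 5, adjusted p = 9.63e-07) were lower. Each list had adjusted p = 0.218 with an estimated correlation. The Hedgehog, elastic fibre, progenitor surface, retinoid, collagen processing, other interstitial collagen, BMP and TGF-beta, complement and proteoglycan lists were lower at adjusted p from 0.000525 to 0.0251 (adjusted p from 0.218 to 0.505 with an estimated correlation).

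Cluster 4 held 81 list genes higher and 73 lower, and outside the clustering 387 and 346. Slit2 (2.08 ± 0.20; 1.79 and 2.76 by library), Gli1 (1.17 ± 0.18), Eln (0.80 ± 0.10), Des (0.73 ± 0.13), Col1a1 (0.46 ± 0.10) and Cd34 (0.45 ± 0.10) were higher, and Pdgfrb (-0.72 ± 0.13) lower. Ly6a (0.15), Pdgfra (0.33), Col15a1 (0.25), Cxcl12 (-0.08), Il33 (0.61), Rspo3 (-0.60) and Hand2 (0.20) were not called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p from 0.0677 to 0.793. In that test the called panel genes had adjusted p of 0.0144 (Cd34) or less. The Hedgehog feedback gene Ptch1 (1.11 ± 0.14) rose with Gli1. The Hedgehog list, with a median of -0.01, was not called by camera on the edgeR fit (adjusted p = 0.0937, or adjusted p = 0.504 with an estimated correlation). Wif1 (7.20 ± 0.42; 6.35 and 8.49 by library), the limb patterning factor Tbx3 (4.19 ± 0.21), Fbn2 (3.61 ± 0.15), the activin subunit Inhba (3.29 ± 0.30; 4.01 and 2.03) and Il11 (a profibrotic cytokine, 3.16 ± 0.19; 2.84 and 3.78) were higher. Scara5 (a ferritin receptor of adventitial fibroblasts, -5.00 ± 0.69; -4.97 and -2.66) was lower. By camera on the edgeR fit, Wnt genes (9 of 20 higher, 2 lower, adjusted p = 3.39e-07) and chemokines and cytokines (7 of 22 and 2, adjusted p = 4.99e-06) were higher, as in Dkk2 (5.06 ± 0.25) and Il34 (2.17 ± 0.15). With an estimated correlation each had adjusted p = 0.4. Notch genes (0 of 9 higher, 6 lower, adjusted p = 0.000213) and interferon genes (1 of 19 and 7, adjusted p = 0.00134) were lower, as in Notch3 (-2.09 ± 0.30) and Ifit1 (-2.43 ± 0.17). Adjusted p of these lists ran from 0.4 to 0.606 with an estimated correlation. Vasoactive, fibrillar collagen, retinoid, collagen processing and complement lists were called at adjusted p from 0.00667 to 0.0244 (adjusted p from 0.4 to 0.504 with an estimated correlation).

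Cluster 7 held 88 list genes higher and 68 lower, and outside the clustering 376 and 296. Rspo3 (1.45 ± 0.19), Cd34 (0.58 ± 0.10) and Col1a1 (0.44 ± 0.10) were higher, and Des (-1.50 ± 0.15), Ly6a (-1.15 ± 0.19) and Cxcl12 (-1.14 ± 0.14) lower. Slit2 (0.23; 0.58 and -1.01 by library), Gli1 (-0.79), Pdgfra (-0.45), Pdgfrb (0.01), Eln (-0.36), Col15a1 (0.35), Il33 (-0.26; 0.22 and -1.42) and Hand2 (-0.35) were not called by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, at adjusted p from 0.0542 to 0.975. In that test the called panel genes had adjusted p of 0.0176 (Col1a1) or less. Scara5 (6.86 ± 0.36), Mfap5 (6.21 ± 0.22; 5.70 and 6.85 by library), Cd55 (a shield against complement, 2.69 and 3.37 by library) and Has1 (2.63 ± 0.12) were higher. Cxcl13 had 1 count in the other clusters and a ratio of 6434 (counting interval 1151 to 254517), at 9.31 and 7.14 by library. Fbn2 (-4.64 ± 0.24) was lower, and so was Wif1, with 2 counts in cluster 7 and a ratio of 80.8 (counting interval 22.3 to 667). By camera on the edgeR fit, collagen processing (5 of 16 higher, 0 lower, adjusted p = 1.14e-06) and proteoglycans (8 of 16 and 1, adjusted p = 1.18e-06) were higher. Each list had adjusted p = 0.268 with an estimated correlation. Progenitor surface genes (7 of 17 and 3, adjusted p = 1.05e-05, or adjusted p = 0.268 with an estimated correlation) were called higher although their median was -0.08, with a mean of 0.87. Lists called with lower members were contractile, interferon and dissociation genes, at adjusted p from 0.00381 to 0.0348 (adjusted p from 0.314 to 0.684 with an estimated correlation). Elastic fibre, Hedgehog and fibrillar collagen lists were called higher at adjusted p from 0.000555 to 0.0373 (adjusted p from 0.314 to 0.562 with an estimated correlation).

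**Figure D5:**
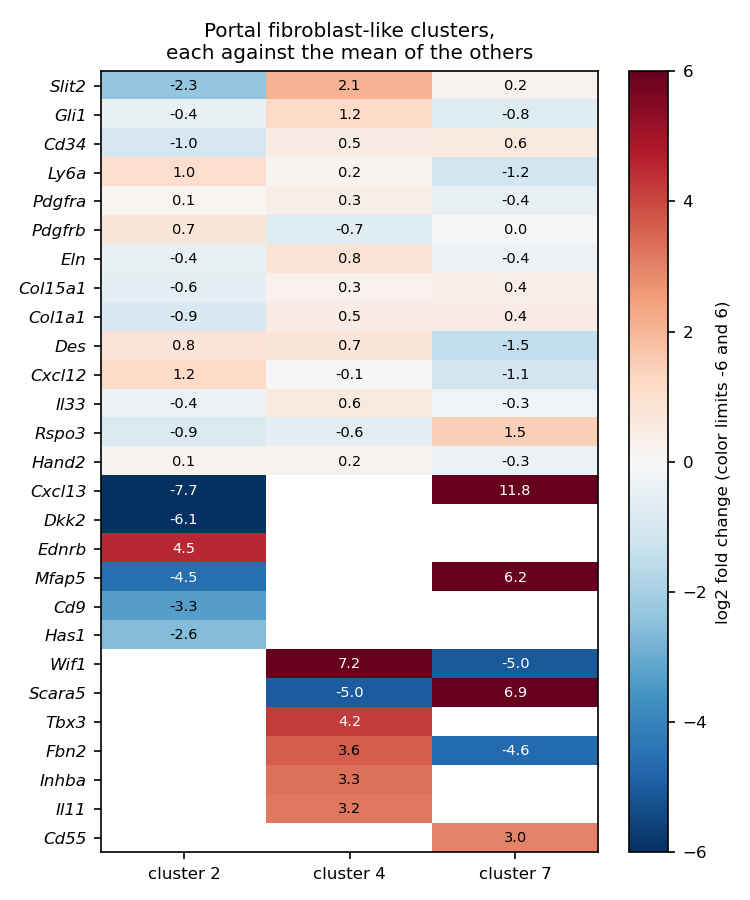
Log2 fold change of the named genes in clusters 2, 4 and 7, each against the mean of the others, with colours limited at 6 in either direction and blank where a gene was not named for that cluster. Slit2 was -2.30 in cluster 2, 2.08 in cluster 4 and 0.23 in cluster 7, and the fitted values of Cxcl13 in clusters 2 and 7 and of Wif1 in cluster 7 rest on 2 or fewer counts on the low side.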

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

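The tests of free RNA against endothelial-like cells and of lost replicate 2 barcodes were chosen after the results they measure were seen, and the other tests before. Results singled out here came from signals outside the class comparisons or the mesenchymal cells the sort was meant to keep.

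A small cluster (cluster 17) made up 1.33% of replicate 1 (63 cells, exact 95% interval 1.02 to 1.69) and 0 of 2109 cells of replicate 2, where a count of 0 has an exact upper limit of 0.175%. It led with H19, the imprinted noncoding RNA of fetal and growing tissue, at 760 CPM against 0.459 and 0 in portal fibroblast-like cells. Ccl11 (4411 against 385 and 326), the matrix proteoglycan Vcan (1014 against 62.9 and 33.5), the hyaluronan synthase Has2 (264 against 4.77 and 5.12) and the Wnt antagonist Wif1 (678 against 54.8 and 29.5) went with it. These genes were picked as the leading ones of the cluster and are given to describe it. Ccl11, Vcan, Has2 and Wif1 are list genes and had no part in forming it.

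What the tables argue against is set out here for that cluster. Doublets would place its median doublet score high among replicate 1 cells, and it lay at percentile 28.4 (0.0184 against 0.0256). That score was read after the 195 highest scores of replicate 1 had been removed, so it speaks only for the cells kept. A shift over the whole of replicate 1 would show in portal fibroblast-like cells, where the leading genes had a median log2 ratio between libraries of 0.65, against the 3.93 of the cluster. Loss of such cells to filtering would leave barcodes in replicate 2, and with every barcode kept there were 0, against 69 in replicate 1. A difference between the animals or the preparations of the libraries remains open and could not be separated from the library, and no biological explanation was tested, since the labels give 1 group.

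Endothelial-like cells made up 2.72% of replicate 1 and 1.99% of replicate 2 although the sort excluded CD31. The unnamed cluster 15, with 8 endothelial markers raised, held a further 0.969% and 1.23% that these shares leave out. Free RNA of different genes would fall into cells independently, so cells picked by other endothelial genes would hold no more Pecam1 than the rest. Cells with 2 or more of the 7 other endothelial markers (306 and 123 cells, picked without clusters) held Pecam1 at 312 and 297 CPM, against 2.81 and 2.39 in cells with none. The lower of these ratios was 111. Doublets with mesenchymal cells would carry collagen, and fibrillar collagens stood at 3.63% of the lowest mesenchymal class in one library and 3.60% in the other. Cells that escaped the gate remain a candidate explanation, untested because surface protein was not analysed here, and no biological explanation was tested.

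Schwann or glial-like cells made up 0.548% of replicate 1 and 0.142% of replicate 2, that is 26 and 3 cells, too few in replicate 2 for a test. Barcodes with over 80% mitochondrial UMIs made up 6.15% of the deposited barcodes of replicate 1 and 3.85% of replicate 2, and were removed before clustering.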

How the results depend on the processing

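Looser naming, the expected doublet rate in both libraries and the count split for shares were chosen after the data had been seen. List calls depended on the correlation assumed. With a correlation estimated per list, 0 of 15 lists stayed called for portal fibroblast-like against stellate-like, 1 of 15 against smooth muscle-like, 0 of 9 for stellate-like against smooth muscle-like, 0 of 11 against mesothelial-like, and 0 of 15, 0 of 9 and 0 of 9 in clusters 2, 4 and 7. At an unadjusted p under 0.05 that camera test had 7, 9, 2, 10, 1, 1 and 3 lists in the same order. Of the called lists fry kept 15, 15, 9, 11, 10, 0 and 6, and in cluster 4 it had 13 lists at an unadjusted p under 0.05. Numbers of called genes outside the clustering moved by more than 1.5 times as follows. Thinned cells gave 1227 higher and 1143 lower against stellate-like cells, 989 and 707 against smooth muscle-like cells, 1060 and 1059 for stellate-like against smooth muscle-like cells, and 841 and 461 against mesothelial-like cells. DESeq2 gave 1461 lower against stellate-like cells, 203 higher and 229 lower in cluster 2, 202 and 180 in cluster 4, and 186 lower in cluster 7. No filter on low counts gave 807 higher in cluster 2, 609 higher in cluster 4, and 551 lower (109 list genes) in cluster 7. Without the replicate block, 289 were lower in cluster 2, and 44 list genes were lower in cluster 7.

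Mean shares moved by more than the SD of the libraries with clustering and naming, for means of the libraries of 35.4% portal fibroblast-like, 24.3% stellate-like, 2.35% endothelial-like and 26.3% unnamed. Portal fibroblast-like cells were 24.0% with the expected doublet rate in both libraries, 23.4% with list genes allowed, 50.6% with looser naming and 47.2% at resolution 0.4. Stellate-like cells were 20.1% with all barcodes, 26.5% with list genes allowed and with looser naming, and 27.7% with a mitochondrial limit of 5%. Endothelial-like cells were 7.54% with all barcodes, 3.01% with the count split, 1.65% with the limit of 5%, 3.60% with no doublet removal and 3.46% at resolution 0.4. Unnamed cells were 28.8% with all barcodes, 37.8% with the expected doublet rate, 36.2% with list genes allowed, 8.82% with looser naming, 20.8% with the limit of 5%, 22.5% with no doublet removal, 10.9% at resolution 0.4 and 23.9% at resolution 1.5. The mesothelial-like mean went from 1.68% to 1.11% with the limit of 5%, within the SD of the libraries (1.04). Pecam1 was found in 3.24% and Epcam in 0.0347% of thinned cells.

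Of 153 named values 125 were called, and of 1508 values from tested alternatives 1458 kept direction and call, 27 lost the call, 18 gained it and 5 reversed. Values named by the rule, beyond the panel, were picked as called, large and the same in direction in both libraries. The number called, and in part the number kept, follow from that choice. Only DESeq2, its size factors in edgeR, no filter on low counts and no replicate block covered all 153 values. Each other tested alternative covered 90 values of the class comparisons, or 86 with thinned cells. Values of the clusters inside the portal fibroblast-like class were therefore not tested under another clustering or naming, the count split or thinned cells. Reversed were Cd34 for stellate-like against smooth muscle-like cells (0.25 with list genes allowed and 0.46 with looser naming, from -2.46) and Col15a1 there (0.0603 with looser naming, from -3.19), and, among values not called, Pdgfrb against stellate-like cells (0.10 at resolution 0.4) and in cluster 7 (-0.0312 with no filter). Without either library only folds with no test could be had. Of the 153 values 52 moved by more than the SD of the libraries without replicate 1 and 29 without replicate 2, and no called value changed sign. For values named by the rule, the unchanged sign was fixed in advance. These single-library folds carry a prior count of 2 that the fitted values lack, so a move can reflect that difference and not the library left out. Wif1 against stellate-like cells, fitted at 8.89, was 7.13 and 6.77 by library, below the fit in both. The libraries lay on opposite sides of 0 for 8 values, none called, among them Slit2 in cluster 7 (0.58 and -1.01) and Il33 in cluster 2 (-0.63 and 0.26).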

Other observations

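Every alternative clustering was looked at after cluster 17 had been seen. Unnamed clusters are described here by levels of list genes and panel genes, given as mean CPM ± SD (n = 2 libraries) and chosen after their values were seen. Cluster 10 (161 cells) held Rgs5 at 11104 ± 228, against 2190 in stellate-like and 2770 in smooth muscle-like cells, with the pericyte receptor Notch3 (951 ± 35.8) and the potassium channel subunit Kcnj8 (206 ± 63.5). Cluster 9 (223 cells) held Col8a1 (a short-chain collagen of vessel intima, 603 ± 107), Vegfd (621 ± 0.845) and Notch3 (575 ± 28.5). Cluster 11 (158 cells) held Itga8 (932 ± 87.2), the neurotrophin Bdnf (273 ± 59.3) and Robo2 (254 ± 65.1). Cluster 3 (686 cells) held Ly6a (1042 ± 19.8), the growth factor Gdf10 (890 ± 43.8) and Cx3cl1 (a membrane-bound attractant of monocytes, 179 ± 5.61), and cluster 6 (364 cells) held the heparin-binding factor Mdk (363 ± 36.8).

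Endothelial-like cells split into cluster 12, with the hepatocyte zonation signals Rspo3 (2627 ± 1640), Wnt2 (456 ± 111) and Wnt9b (381 ± 100), and cluster 18, with netrin Ntn1 (475 ± 95.5) and lymphatic-type leading genes. Rspo3 differed between the libraries, at 3787 and 1467. The unnamed cluster 15 carried the Notch ligand Dll4 (354 ± 3.54) and the interferon-induced chemokine Cxcl9 (1446 and 416 in the libraries). Rspo3 thus had sources in both stellate-like and endothelial-like cells, and the portal fibroblast-like clusters held little of it. None of these levels was tested between clusters.

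Antigen presentation and interferon genes were lower in portal fibroblast-like than in stellate-like cells by camera on the edgeR fit, and dissociation genes moved the same way. These lists had adjusted p = 0.208 and adjusted p = 0.412 with an estimated correlation, so the list calls were lost there. A difference in depth was predicted to end the calls of interferon genes once every cell is thinned to the same depth. Of the 18 called lower, 18 were still so. That cannot decide on depth, since each sum was scaled to its total with or without thinning. Over all lists 106 genes were called lower with thinned cells, against 110 without thinning. Dissociation genes were not put to this test. At resolution 1.5 a stellate-like cluster with Ifit3b, Ifit1 and Ifit3 among its leading genes held 137 cells (2.89%) of replicate 1 and 10 (0.474%) of replicate 2. Another stellate-like cluster of that setting with Ifit3 among its leading genes was even (10.8% and 11.3%), and clusters led in part by Ifit genes in other settings differed less (5.64% and 3.05% with a mitochondrial limit of 5%, 4.28% and 2.13% with list genes allowed). The lower level may reflect cell identity or exposure during isolation, and these remain open because each class passed through the same preparation. No biological explanation was tested.

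In each of the 11 settings of clustering and naming, a cluster with H19 among its 2 leading genes held 0 replicate 2 cells. Looser naming kept the clusters of the first setting, and every setting used the same 2 libraries.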
